A study of Mus musculus with 45 samples.

How the data were processed

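The data are 45 Agilent arrays with 2 dyes, on which Cy5 carries RNA of 1 lung and Cy3 a mouse reference RNA pooled from cell lines, with no dye swap. Per the file headers the scans were read with Agilent Feature Extraction 11.0.1.1, protocol GE2_1100_Jul11. The deposited scanner files give intensity as median pixel signals and processed signals, a log10 ratio set to 0 on some spots, and other columns that are 0 or 1 flags. They hold no mean signals, so the median signals were used. The authors' series value table is in log2 ratio. The authors do not state how it was made; on every array it correlates at 0.99 or more with a loess-normalized ratio without background correction.

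Groups were taken from the sample titles, which give material, dose and a replicate number from 1 to 45. For 4 arrays (replicates 17, 42, 44 and 45) the treatment characteristic names another material than the title; they stay in the group of the title, and both other choices are among the alternatives. Per the labels each group has 5 animals, but the controls have 6 arrays and NRCWE-046 at 54 µg has 4. The labels do not say outright that each array is a separate animal, and the vehicle of the controls is not stated.

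Signals were background-corrected with normexp at an offset of 50 and normalized by loess within each array (limma 3.58.1 in R 4.3.3, with data.table version 1.17.8). Control spots and spots marked by the scanner software were left out, spots of 1 probe were averaged, and probes well above background in the lung channel on at least 4 arrays were kept. For each gene the probe with the highest mean signal was used. Of 62976 features on the array 59305 are not controls, with 55681 distinct probes, of which 27235 pair with a gene symbol (20660 distinct symbols) and 28446 do not. The filter kept 48918 probes, which gave 33718 features to test, 19063 of them with a symbol; 8814 had several kept probes. In 587 probes 596 values were missing. Symbols come from the probe's transcript accession and the annotation of mouse assembly GRCm38.p6. The lowest correlation between any pair of arrays was 0.748 for normalized ratios and 0.682 for raw ratios.

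All 9 groups entered 1 limma fit with 36 residual degrees of freedom, or 40 with the prior. Each group was tested against the controls, each material between its doses, and each pair of materials at each dose. F tests asked whether the materials differ at 18 µg, at 54 µg, and in their dose effect. Adjusted p values are Benjamini-Hochberg values within a comparison. Where slides hold several groups, differences were also taken within slides. The genes checked there were called on the same arrays, so their direction is largely fixed beforehand and is no separate test. There are 10 slides, of which 9 hold more than 1 array and 6 hold a control, and 7 scan dates.

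The gene lists, the comparisons and the rule for named genes were fixed before the data were examined. There are 25 pathway lists and 24 cell type marker lists. They were tested with camera at a preset correlation of 0.01, on lists with at least 4 measured genes. Against control 163 list results passed over the 8 comparisons, between doses 76 and between materials 182; with an estimated correlation 48, 8 and 18 passed. Under random regrouping of the arrays, camera at the preset correlation still passed medians of 71, 37 and 104. The regrouped arrays kept their real exposures and slide effects, so these medians are no rate of false calls. A list score per array (mean log2 ratio of the list's genes) was compared by 2-sided exact permutation. It called 69 results against control, 10 between doses (all with NRCWE-049) and 0 between materials. The smallest p it allows is 0.00216 for 5 against 6 arrays, 0.00476 for 4 against 6 and 0.00794 for 4 against 5. It is also 0.00794 for 5 against 5, where each split has a mirror image with the same difference. Several lists must reach this floor before any passes the adjustment, so the 0 between materials is weak evidence of no difference.

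The text names the called genes with the highest and lowest log2 differences that lie on 1 side of the other group's mean in every animal: 12 and 8 for each group at 54 µg, 5 and 3 at 18 µg, 3 and 3 for doses and pairs, and the 5 smallest p values of each F test. It may also name up to 4 called members of each list that passed, and a panel of 18 genes in every group. Where a group is not well above background on all its arrays, the text says so for some genes only. Among panel genes named as raised, Il6 was well above background on 1 of 6 control arrays, Cxcl1 on 3, Cxcl5 on 4 and Arg1 on 5. Their changes against control therefore rest on a baseline that lies partly near background. Some genes that the rule selects are not reported here.

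Because all comparisons with control use the same arrays, shared calls were set beside lists drawn independently, simulated arrays without effects, and splits that give each material its own controls. Alternatives tried were no background correction, the scanner log ratio centred on its median, the lung channel alone, the authors' value table, 2 other filters on dim probes, the mean of a gene's probes, slide as a fixed or random block, scan date as a block, array weights, only the groups of a comparison in the fit, both readings of the 4 conflicting labels, an estimated correlation in camera, and every array left out in turn. Leaving out slide 10 was added after the data were seen.

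Before use the fit was tried on simulated arrays of 33718 genes, with 50 of them changed at each of the folds given next. At changes of 1.5, 2, 3 and 5-fold it recovered 70, 96, 100 and 100% for NRCWE-046 at 18 µg against control, 70, 94, 94 and 98% for NRCWE-047, 74, 94, 96 and 100% for NRCWE-048 and 66, 92, 96 and 100% for NRCWE-049. At 54 µg against control it recovered 76, 96, 98 and 100% for NRCWE-046, 78, 96, 98 and 100% for NRCWE-047, 74, 92, 100 and 100% for NRCWE-048 and 70, 90, 100 and 100% for NRCWE-049. In these 8 comparisons 5 to 15 unchanged genes were called. Between doses it recovered 66, 96, 98 and 100% for NRCWE-046, 76, 94, 96 and 100% for NRCWE-047, 60, 94, 96 and 98% for NRCWE-048 and 66, 88, 100 and 100% for NRCWE-049.

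For pairs at 18 µg, with 33718 genes and the same folds, it recovered 64, 92, 96 and 100% for NRCWE-047 against NRCWE-046, 72, 92, 98 and 100% for NRCWE-048 against NRCWE-046, 58, 94, 100 and 100% for NRCWE-049 against NRCWE-046, 68, 92, 98 and 100% for NRCWE-048 against NRCWE-047, 70, 92, 98 and 100% for NRCWE-049 against NRCWE-047 and 76, 90, 96 and 98% for NRCWE-049 against NRCWE-048. At 54 µg it recovered 64, 92, 98 and 98% for NRCWE-047 against NRCWE-046, 68, 92, 96 and 100% for NRCWE-048 against NRCWE-046, 70, 86, 98 and 100% for NRCWE-049 against NRCWE-046, 58, 94, 100 and 100% for NRCWE-048 against NRCWE-047, 78, 94, 96 and 100% for NRCWE-049 against NRCWE-047 and 66, 94, 98 and 100% for NRCWE-049 against NRCWE-048. The F tests recovered 62, 100, 94 and 98% at 18 µg, 78, 88, 98 and 100% at 54 µg and 44, 74, 92 and 96% for the dose effect between materials, with 12, 3 and 13 unchanged genes called. In all these simulations the noise was independent between genes and arrays and held no slide effect. Recovery and false calls in the real arrays may therefore be worse.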

Results

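The series asks how strongly 4 nanomaterials, given here only by their codes NRCWE-046, NRCWE-047, NRCWE-048 and NRCWE-049, perturb pathways in the mouse lung. Lungs of female C57BL/6 mice were taken 24 h after 1 instillation into the trachea of 18 or 54 µg per animal, with 6 control arrays at 0 µg. Each treated group has 5 arrays, except NRCWE-046 at 54 µg with 4. The arrays carry numbers from 1 to 45 without repeats and are treated as separate animals. All changes are log2 differences of the lung over reference ratio, and a gene is called at an adjusted p under 0.05 in limma.

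At 54 µg all 4 materials raised acute phase and CC chemokine genes. Saa3, an acute phase serum amyloid A gene, stood above the control mean by 6.89 (SD 0.43, n = 4) with NRCWE-046, 7.71 (SD 0.75, n = 5) with NRCWE-047, 5.59 (SD 2.84, n = 5) with NRCWE-048 and 7.21 (SD 0.41, n = 5) with NRCWE-049. The 6 controls themselves had an SD of 1.87 for Saa3. In total 56 genes were called higher and 10 lower with all 4 materials at 54 µg. Among the higher ones were Saa1 and Saa2, the monocyte chemoattractants Ccl2, Ccl7 and Ccl12, the interferon-induced chemokine Cxcl10, Il1b, Lcn2 (a siderophore-binding protein of neutrophils and epithelium), Timp1 (an inhibitor of matrix proteases), the NF-kB feedback gene Tnfaip3, and Socs3 and Relb. The lower ones included Ephx1, an epoxide hydrolase, and Bcan, a brain proteoglycan. At 18 µg, 3 genes were called higher in all 4 materials: Saa3, Lcn2 and Ly6f. The surfactant gene Sftpc and the club cell gene Scgb1a1 passed the test in none of the 8 comparisons with control, where limma had between 1152 and 6263 genes at an unadjusted p under 0.05. Their group means at 54 µg lay between -0.19 and 0.11 for Sftpc and between -0.37 and 0.22 for Scgb1a1.

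**Figure D1:**
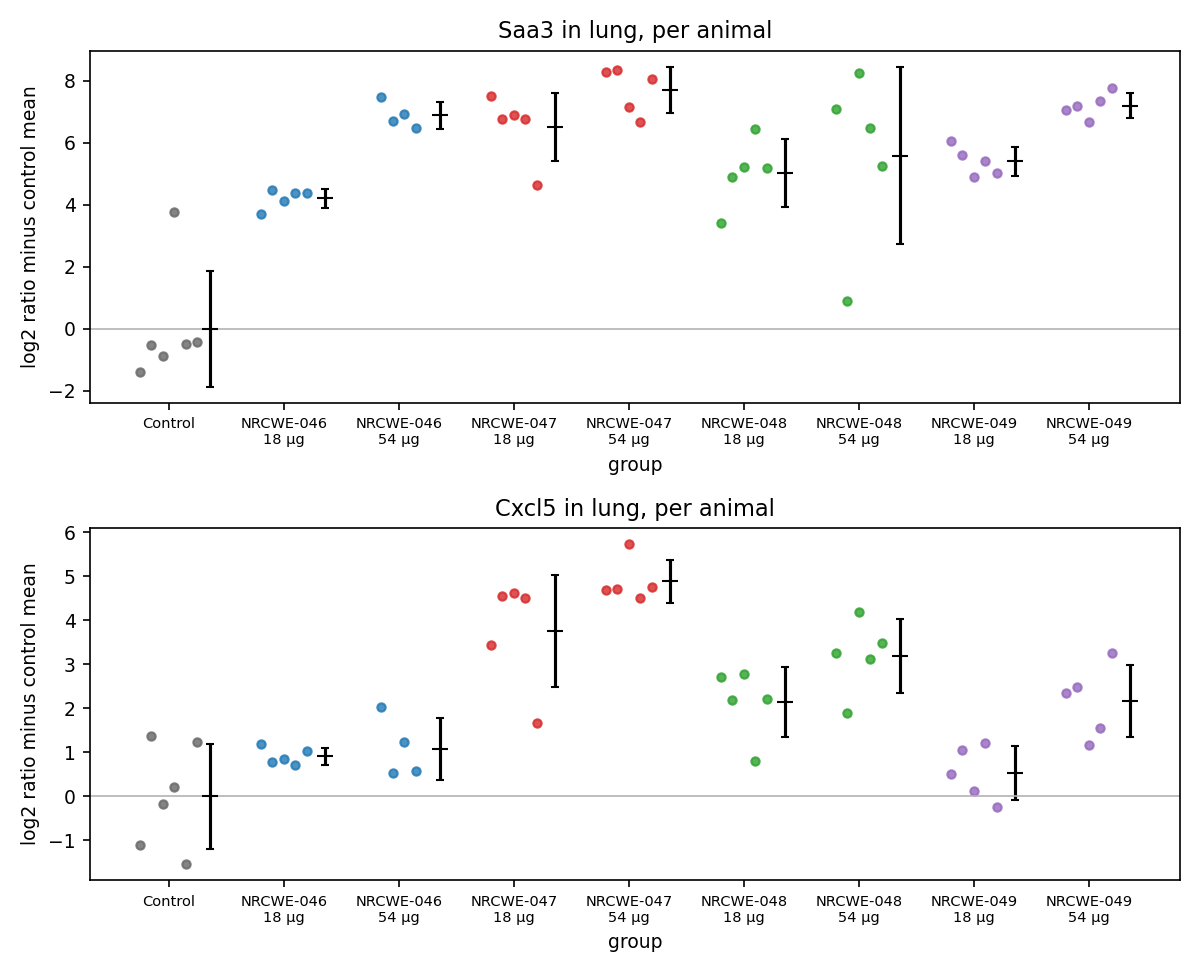
Saa3 (upper) and Cxcl5 (lower) per animal by group, as the log2 ratio minus the control mean; dots are animals, and the black mark with its bar is the group mean with its SD. Saa3 lies above the control mean in every treated animal, while mean Cxcl5 in the treated groups runs from 0.53 with NRCWE-049 at 18 µg to 4.88 with NRCWE-047 at 54 µg.

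NRCWE-047 at 54 µg raised chemokines of neutrophils and monocytes together with genes of protein folding and sterol synthesis. Cxcl5, a neutrophil chemoattractant, rose by 4.88 (SE 0.49, adjusted p = 1.94e-08, higher in 5 of 5 animals), beside Cxcl1 at 2.63 (SE 0.48). Among the 6 control arrays Cxcl5 was well above background on 4 and Cxcl1 on 3. Of the 7 measured neutrophil chemoattractants 3 rose (4 adjusted over the list alone; list adjusted p = 2.3e-08). The third was Cxcl3 at 1.27 (SE 0.12), which was not well above background on any of the 6 control arrays. Of 13 CC chemokines 9 rose (9 adjusted over the list alone; list adjusted p = 1.24e-15), led by Ccl7 at 3.90 (SE 0.46) and Ccl2 at 3.59 (SE 0.43). Of 20 acute phase genes 13 rose (15 adjusted over the list alone; list adjusted p = 1.33e-24), and of 17 NF-kB feedback and Toll-like genes 10 rose (14 adjusted over the list alone; list adjusted p = 8.04e-20). In the sterol synthesis list 16 of 21 genes rose (16 adjusted over the list alone; list adjusted p = 1.22e-20), such as Hmgcs1 at 1.03 (SE 0.17) and Sqle at 0.95 (SE 0.16). In the unfolded protein response list 10 of 16 rose and 1 fell (11 and 2 adjusted over the list alone; list adjusted p = 7.45e-15), with the chaperone Hspa5 at 1.49 (SE 0.19). Metallothionein Mt2 rose by 2.70 (SE 0.38), and 5 of 11 genes of metal handling rose (5 adjusted over the list alone, with 1 lower; list adjusted p = 1.84e-05). The cytokine Il6 rose by 2.22 (SE 0.33), over controls with 1 of 6 arrays well above background.

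Lower with NRCWE-047 at 54 µg were Dbp at -2.07 (SE 0.62), an output gene of the circadian clock, Fabp1 at -2.03 (SE 0.54), a fatty acid binding protein listed here with alveolar macrophages, Zbtb16 at -1.98 (SE 0.33) and Tsc22d3 at -1.43 (SE 0.29), both induced by glucocorticoids. Ephx1 fell by 1.21 on the log2 scale (SE 0.13), and 3 of 15 genes of xenobiotic metabolism fell (7 adjusted over the list alone; list adjusted p = 3.2e-08). Among 16 clock genes 6 fell and 2 rose (10 and 4 adjusted over the list alone; list adjusted p = 0.00159, adjusted p = 0.102 with an estimated correlation). Of 14 alveolar macrophage markers 3 fell (6 adjusted over the list alone; list adjusted p = 6.63e-05, adjusted p = 0.299 with an estimated correlation), and 5 of 18 neutrophil markers rose (6 adjusted over the list alone, with 1 lower; list adjusted p = 4.38e-05, adjusted p = 0.178 with an estimated correlation). Monocyte markers (3 of 10, 3 adjusted over the list alone; list adjusted p = 0.000787, adjusted p = 0.143 with an estimated correlation) were higher. So were smooth muscle cell markers (1 of 8, 3 adjusted over the list alone; list adjusted p = 0.0089, adjusted p = 0.341 with an estimated correlation). Club cell markers (2 of 8, 2 adjusted over the list alone; list adjusted p = 0.00909, adjusted p = 0.264 with an estimated correlation) were lower. So were fibroblast markers (1 of 10, 1 adjusted over the list alone; list adjusted p = 0.0116, adjusted p = 0.264 with an estimated correlation). In all, 1797 genes were called, 1133 higher and 664 lower, and 63% of the calls were higher. Scored on the lung channel alone the higher share was 50.7%, and 54.3% in the authors' value table. Fitting slide as a block gave 3720 calls, 1778 of them among the 1797, and 3343 without slide 10 (1523 higher, 1820 lower). With only the groups of the contrast in the fit there were 987. Within the 4 slides that hold a control and this group, 95.6 to 99.9% of the called genes kept their direction and Saa3 differed by 7.54 to 9.68. These genes were called with the arrays of these slides included, so this is no separate test. With the slide block Dbp stood at -1.65 (adjusted p = 0.0572).

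NRCWE-049 at 54 µg changed 2500 genes, of which 1702 were higher and 798 lower. That is more than with NRCWE-047 as the titles group the arrays, but not without the 4 arrays with conflicting labels (3703 against 4272) or with groups by the treatment characteristic (2606 against 3791). Of these 4 arrays 3 are on slide 10. Without slide 10 NRCWE-049 again had more (4172 against 3343), as with a slide block (4679 against 3720). Both readings of the labels are therefore mixed with the slide 10 effect. Cxcl5 stood 1.04, 1.02 and 3.50 above the control mean on replicates 17, 42 and 44. The lowest NRCWE-047 array had 1.66 at 18 µg and 4.51 at 54 µg. Saa3 was lower too on replicates 42 and 44 (4.38 and 5.25, lowest 4.64 and 6.67), but not on replicate 17 (5.61). Control 45 had Saa3 at -0.44. These are 2 genes picked from the panel, and which label is right was not tested. Interferon-induced genes rose nearly throughout the list: 19 of 21 (20 adjusted over the list alone; list adjusted p = 2.66e-22), with Cxcl10 at 4.35 (SE 0.58), the antiviral sensor Zbp1 at 1.98 (SE 0.27), Oas1a at 1.93 (SE 0.35) and Isg15 at 1.91 (SE 0.45). Acute phase genes rose, 13 of 20 (17 adjusted over the list alone; list adjusted p = 3.85e-18), and of 13 CC chemokines 9 (10 adjusted over the list alone; list adjusted p = 1.44e-14), among them the eosinophil chemoattractant Ccl24 at 3.61 (SE 0.60). Of 10 monocyte markers 5 rose (6 adjusted over the list alone; list adjusted p = 7.52e-06), with Plac8 at 1.57 (SE 0.26) and the Ccl2 receptor Ccr2 at 1.39 (SE 0.33). Of 21 matrix and fibrosis genes 9 rose (9 adjusted over the list alone, with 1 lower; list adjusted p = 7.52e-06), with Timp1 at 4.56 (SE 0.52) and the collagen Col3a1 at 1.09 (SE 0.18). Il1b rose by 2.37 (SE 0.29), Il6 by 2.36 (SE 0.33), and Arg1, an arginase of alternatively activated macrophages, by 2.42 (SE 0.45). Hmox1, a haem oxygenase induced by oxidative stress, stood at 1.60 (SD 1.19, n = 5) and did not pass the test. Sterol synthesis (13 of 21 higher, 16 and 1 lower adjusted over the list alone; list adjusted p = 1.45e-12) and the unfolded protein response (9 of 16 higher, 10 and 2 lower adjusted over the list alone; list adjusted p = 1.11e-07) rose here too.

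Lower with NRCWE-049 at 54 µg were genes that handle foreign compounds and respond to glucocorticoids. Aldh1a1, a retinal dehydrogenase listed with club cells, fell by 1.82 (SE 0.24), the glutathione transferase Gsta3 by 1.54 (SE 0.21), and Tsc22d3 by 1.67 (SE 0.29), all on the log2 scale. Of 15 xenobiotic metabolism genes 5 fell (9 adjusted over the list alone; list adjusted p = 1.24e-08); Cyp1a1, at -0.75 (SE 0.19), was well above background on 0 of 5 treated arrays. Of 10 glucocorticoid-responsive genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; list adjusted p = 0.00379, adjusted p = 0.289 with an estimated correlation). Of 14 alveolar macrophage markers 2 fell (3 adjusted over the list alone; list adjusted p = 0.00379, adjusted p = 0.455 with an estimated correlation). Of 18 neutrophil markers 6 rose (9 adjusted over the list alone; list adjusted p = 6.37e-06, adjusted p = 0.121 with an estimated correlation), and 2 of 7 neutrophil chemoattractants rose (4 adjusted over the list alone; list adjusted p = 0.00502, adjusted p = 0.0802 with an estimated correlation). Club cell markers (2 of 8, 2 adjusted over the list alone; list adjusted p = 0.0026, adjusted p = 0.182 with an estimated correlation) and fibroblast markers (2 of 10, 2 adjusted over the list alone; list adjusted p = 0.0166, adjusted p = 0.291 with an estimated correlation) were lower. B cell markers were higher (1 of 11, 2 adjusted over the list alone; list adjusted p = 0.00175, adjusted p = 0.394 with an estimated correlation). Of all calls 68.1% were higher, against 51.9% on the lung channel alone and 55.5% in the authors' value table. Under a slide block 4679 were called, 2329 of them among the 2500, and 4172 without slide 10 (2152 higher, 2020 lower). With only the groups of the contrast in the fit there were 1560. Within 3 slides 96.8 to 99% of the called genes kept their direction, and Saa3 differed by 3.60 to 8.60.

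NRCWE-046 at 54 µg raised acute phase genes and chemokines. Saa3 rose by 6.89 (SE 0.82, adjusted p = 7.16e-06, higher in 4 of 4 animals), Saa1 by 4.50 (SE 0.64) and Timp1 by 3.69 (SE 0.55). Of 20 acute phase genes 11 rose (14 adjusted over the list alone; list adjusted p = 9.47e-21), and of 13 CC chemokines 8 (9 adjusted over the list alone; list adjusted p = 5.81e-14), with Ccl7 at 2.37 (SE 0.49) and Ccl4 at 2.18 (SE 0.46). Of 29 cell cycle genes 7 rose (10 adjusted over the list alone; list adjusted p = 2.17e-08, adjusted p = 0.139 with an estimated correlation), among them the replicative helicase genes Mcm3 at 1.19 (SE 0.19), Mcm6 at 1.14 (SE 0.16) and Mcm5 at 1.03 (SE 0.15). Cxcl5 stood at 1.08 (SD 0.70, n = 4) and did not pass the test, nor did the list of 7 neutrophil chemoattractants (list adjusted p = 0.215). Of 17 NF-kB feedback and Toll-like genes 3 rose (11 adjusted over the list alone; list adjusted p = 1.18e-07, adjusted p = 0.0546 with an estimated correlation). Neutrophil markers (3 of 18 higher, 4 adjusted over the list alone; list adjusted p = 3.73e-05, adjusted p = 0.164 with an estimated correlation) and monocyte markers (2 of 10 higher, 5 adjusted over the list alone; list adjusted p = 0.00026, adjusted p = 0.0915 with an estimated correlation) were higher. Club cell markers (1 of 8, 1 adjusted over the list alone; list adjusted p = 0.0303, adjusted p = 0.371 with an estimated correlation) and fibroblast markers (1 of 10, 1 adjusted over the list alone; list adjusted p = 0.0208, adjusted p = 0.305 with an estimated correlation) were lower. Alveolar type 2 cell markers passed as higher (list adjusted p = 0.00602, 0.441 with an estimated correlation, 0.29 with a slide block). Skeletal muscle markers passed as lower (list adjusted p = 0.0352, 0.209 with an estimated correlation, 0.197 with a slide block). Of 21 interferon-induced genes 3 rose (14 adjusted over the list alone; list adjusted p = 5.26e-13, adjusted p = 0.0915 with an estimated correlation), and of 16 unfolded protein response genes 4 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 3.93e-07). The carboxylesterase Ces1f fell by 1.82 (SE 0.51), the glutathione transferases Gsta2 by 1.21 (SE 0.31) and Gstm1 by 1.06 (SE 0.21), and Aldh1a1 by 1.15 (SE 0.25), on the log2 scale.

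In all, 600 genes were called with NRCWE-046 at 54 µg, 497 higher and 103 lower, so that 82.8% were higher (67.6% on the lung channel alone, 65.1% in the authors' value table). The slide block gave 1298 calls, 569 of them among the 600, and 1102 without slide 10 (728 higher, 374 lower). With only the groups of the contrast in the fit there were 317. Within 2 slides 99.7 to 100% of the called genes kept their direction, and Saa3 differed by 6.96 to 8.02. The count was 397 without control 9, 328 without control 12, and 214, 230 and 306 without replicates 15, 19 and 38 of the group.

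With NRCWE-048 at 54 µg, 96 genes passed, 79 higher and 17 lower. Saa3 rose by 5.59 (SE 0.77, adjusted p = 0.000128, higher in 5 of 5 animals), Cxcl5 by 3.19 (SE 0.49), Cxcl10 by 2.86 (SE 0.58) and Ccl2 by 2.35 (SE 0.43). Acute phase genes rose, 6 of 20 (13 adjusted over the list alone; list adjusted p = 8.58e-20), of 17 NF-kB feedback and Toll-like genes 6 (10 adjusted over the list alone; list adjusted p = 5.41e-16), and of 21 sterol synthesis genes 5 (16 adjusted over the list alone; list adjusted p = 2.76e-19). Camera passed 21 of 49 lists here, but the exact permutation test of the list scores per array passed 0. The adjusted p values of this exact test were 0.119 for acute phase, 0.0882 for NF-kB feedback and 0.0882 for sterol synthesis. The transcription factor genes Egr1 and Nr4a1 rose by 2.05 (SE 0.25) and 1.74 (SE 0.26). The alveolar macrophage list was lower, with 0 of 14 members called (4 lower adjusted over the list alone; list adjusted p = 6.88e-05, adjusted p = 0.394 with an estimated correlation). Markers of neutrophils (1 of 18 called; list adjusted p = 0.00887, adjusted p = 0.488 with an estimated correlation), monocytes (0 of 10; list adjusted p = 0.00792, adjusted p = 0.312 with an estimated correlation) and B cells (0 of 11; list adjusted p = 0.00631, adjusted p = 0.511 with an estimated correlation) were higher as lists, and fibroblast markers lower (0 of 10; list adjusted p = 0.0471, adjusted p = 0.477 with an estimated correlation). With slide as a block the fibroblast list had an adjusted p of 0.0742 in camera. Bcan fell by 1.42 (SE 0.29) and Thbd, the anticoagulant thrombomodulin, by 0.67 (SE 0.16), on the log2 scale. One animal, replicate 14, stood at 0.26 for Lcn2 where the other 4 lay between 1.73 and 2.17.

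The share of higher calls with NRCWE-048 at 54 µg was 82.3%, against 71.7% on the lung channel alone and 66.4% in the authors' value table. Fitting slide as a block gave 559 calls, 96 of them among the 96, and 452 without slide 10 (231 higher, 221 lower). The count fell to 1 with only the groups of the contrast in the fit and to 46 with groups by the treatment characteristic. Within 4 slides 92.7 to 100% of the called genes kept their direction, and Saa3 differed by 1.43 to 8.51. Single animals moved the count: it was 508 without replicate 14, 17, 13 and 36 without replicates 7, 20 and 31, 34, 41, 53, 152 and 183 without controls 9, 12, 29, 33 and 45, and 168 without NRCWE-046 18 µg replicate 42.

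**Figure D2:**
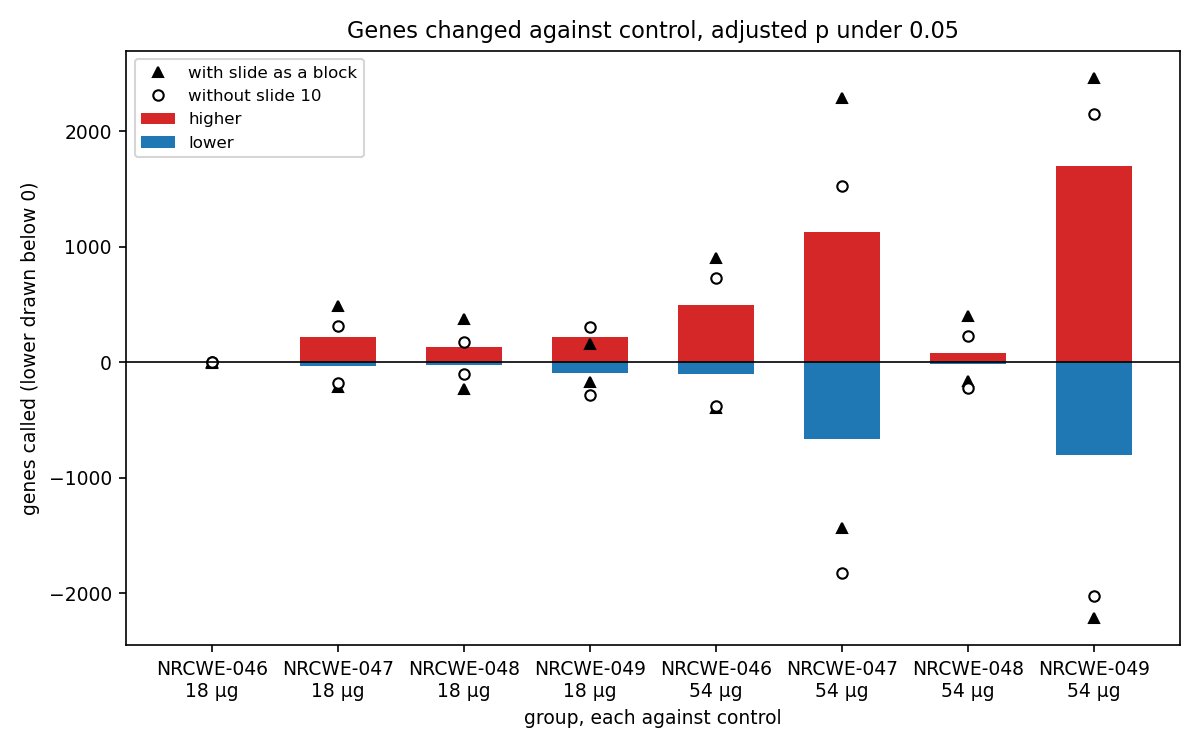
Genes called higher (red bars) and lower (blue bars, drawn below 0) in each group against control, with the counts under a slide block (triangles) and without slide 10 (circles). The counts run from 4 with NRCWE-046 at 18 µg to 2500 with NRCWE-049 at 54 µg.

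NRCWE-047 at 18 µg raised acute phase, chemokine, interferon-induced and unfolded protein response genes. Saa3 rose by 6.52 (SE 0.77, adjusted p = 5.86e-06, higher in 5 of 5 animals), Cxcl5 by 3.75 (SE 0.49), Cxcl10 by 3.26 (SE 0.58) and Timp1 by 3.14 (SE 0.52). Of 20 acute phase genes 9 rose (14 adjusted over the list alone; list adjusted p = 4.8e-26), of 13 CC chemokines 6 (9 adjusted over the list alone; list adjusted p = 7.98e-18), of 21 interferon-induced genes 6 (18 adjusted over the list alone; list adjusted p = 4.8e-26) and of 16 unfolded protein response genes 6 (9 and 1 lower adjusted over the list alone; list adjusted p = 1.57e-13). Among the last were Hspa5 at 1.14 (SE 0.19) and Creld2 at 0.84 (SE 0.12), both of the endoplasmic reticulum. Neutrophil markers (2 of 18, 5 adjusted over the list alone; list adjusted p = 7.05e-06, adjusted p = 0.119 with an estimated correlation) and monocyte markers (1 of 10, 5 adjusted over the list alone; list adjusted p = 1e-06, adjusted p = 0.0217 with an estimated correlation) were higher. The clock repressors Nr1d1 and Nr1d2 fell by 1.83 (SE 0.44) and 1.28 (SE 0.31) on the log2 scale. In all, 255 genes were called, 224 higher and 31 lower, with 87.8% higher under the main scaling. Under a slide block 700 were called, 252 of them among the 255, and 493 without slide 10 (315 higher, 178 lower), against 6 with only the groups of the contrast in the fit. Within 4 slides 85.8 to 100% kept their direction and Saa3 differed by 5.12 to 8.91. The count was 68, 67, 91, 98 and 609 without replicates 5, 13, 22, 32 and 41, 123, 159 and 152 without controls 9, 12 and 45, and 393 without NRCWE-046 18 µg replicate 42.

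NRCWE-049 at 18 µg raised Saa3 by 5.40 (SE 0.77, adjusted p = 0.000242, higher in 5 of 5 animals), Saa1 by 3.37 (SE 0.60), Timp1 by 2.71 (SE 0.52) and Cxcl10 by 2.48 (SE 0.58). Of 21 interferon-induced genes 3 rose (17 adjusted over the list alone; list adjusted p = 1.72e-14, adjusted p = 0.303 with an estimated correlation), and of 20 acute phase genes 5 (10 adjusted over the list alone; list adjusted p = 2.06e-11, adjusted p = 0.182 with an estimated correlation). Of 29 cell cycle genes 4 rose (6 adjusted over the list alone; list adjusted p = 0.0239, adjusted p = 0.622 with an estimated correlation), among them Mcm3 at 0.96 (SE 0.18). Markers of neutrophils (1 of 18, 3 adjusted over the list alone; list adjusted p = 0.039, adjusted p = 0.564 with an estimated correlation), B cells (0 of 11, 0 adjusted over the list alone; list adjusted p = 0.0446, adjusted p = 0.622 with an estimated correlation) and alveolar type 2 cells (0 of 11, 2 adjusted over the list alone; list adjusted p = 0.0138, adjusted p = 0.525 with an estimated correlation) were higher as lists. With slide as a block these lists had adjusted p values of 0.341, 0.162 and 0.0778 in camera. Fibroblast markers were lower (1 of 10, 1 adjusted over the list alone; list adjusted p = 0.0468, adjusted p = 0.521 with an estimated correlation). Gdpd2 fell by 1.46 (SE 0.33) and Cdkn1a, a cell cycle inhibitor, by 1.56 (SE 0.34) on the log2 scale; a second Cdkn1a probe gave -0.20. Of 309 genes called 221 were higher and 88 lower, a higher share of 71.5% against 45.3% on the lung channel alone and 53.2% in the authors' value table. A slide block gave 327 calls, 129 of them among the 309, and 590 without slide 10 (305 higher, 285 lower), against 54 with only the groups of the contrast in the fit and 65 with groups by the treatment characteristic. Within 2 slides 98.4 to 99% kept their direction and Saa3 differed by 5.49 to 6.30. The count was 37, 80, 113, 162 and 157 without replicates 1, 17, 26, 27 and 39, 109, 57, 190 and 85 without controls 9, 12, 29 and 45, and 589 without NRCWE-046 18 µg replicate 42.

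With NRCWE-048 at 18 µg Saa3 rose by 5.03 (SE 0.77, adjusted p = 0.00168, higher in 5 of 5 animals), the anion exchanger Slc26a4 by 3.28 (SE 0.68), Saa1 by 2.86 (SE 0.60) and Timp1 by 2.58 (SE 0.52). Acute phase genes rose, 4 of 20 (13 adjusted over the list alone; list adjusted p = 1.23e-15). Of 13 CC chemokines 2 rose, Ccl17 at 1.79 (SE 0.39) and Ccl9 at 1.07 (SE 0.26) (9 adjusted over the list alone; list adjusted p = 1.19e-11, adjusted p = 0.0524 with an estimated correlation). Of 14 complement genes 3 rose (3 adjusted over the list alone; list adjusted p = 1.28e-07, adjusted p = 0.119 with an estimated correlation), with C3 at 1.44 (SE 0.23) and Cfb at 1.20 (SE 0.28). Markers of monocytes (0 of 10, 0 adjusted over the list alone; list adjusted p = 0.00528, adjusted p = 0.251 with an estimated correlation) and eosinophils (0 of 7, 0 adjusted over the list alone; list adjusted p = 0.0092, adjusted p = 0.209 with an estimated correlation) were higher as lists. Club cell markers were lower (0 of 8, 2 adjusted over the list alone; list adjusted p = 0.00605, adjusted p = 0.251 with an estimated correlation). In all, 150 genes were called, 131 higher and 19 lower; 87.3% were higher, against 67.1% on the lung channel alone and 71% in the authors' value table. The slide block gave 602 calls, 140 of them among the 150, and 280 without slide 10 (176 higher, 104 lower). Limma called 0 with only the groups of the contrast in the fit (2925 genes had an unadjusted p under 0.05 in the fit of all groups) and 80 with groups by the treatment characteristic. Within 3 slides 99.3 to 100% kept their direction and Saa3 differed by 1.43 to 6.31. The count was 233, 38, 14 and 43 without replicates 2, 6, 24 and 35, 75, 40, 228 and 80 without controls 9, 12, 33 and 45, 227 without NRCWE-048 54 µg replicate 14 and 248 without NRCWE-046 18 µg replicate 42.

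NRCWE-046 at 18 µg changed 4 genes, all higher: Saa3 at 4.21 (SE 0.77, adjusted p = 0.0285), Ly6f at 1.63 (SE 0.29, adjusted p = 0.0278) and Lcn2 at 1.39 (SE 0.24, adjusted p = 0.0218), each higher in 5 of 5 animals, and 1 feature without a gene symbol. Of 20 acute phase genes 2 rose (6 adjusted over the list alone; list adjusted p = 1.82e-12, adjusted p = 0.108 with an estimated correlation). Of 49 lists 16 passed here, 0 with an estimated correlation and 0 in the exact permutation test of the list scores. Fitting slide as a block gave 3 calls, 2 of them among the 4, and Saa3 had an adjusted p of 0.0893; without slide 10, with only the groups of the contrast in the fit, or with groups by the treatment characteristic limma called 0, while 1152 genes had an unadjusted p under 0.05 with all arrays. Of the calls 100% were higher, against 66.7% on the lung channel alone. Within 4 slides 100% kept their direction and Saa3 differed by 0.62 to 5.10. The count was 0 without replicates 8, 21, 34 or 42 or controls 9, 12, 37 or 45, 2 without control 29 or replicate 30, and 7 without control 33, NRCWE-047 18 µg replicate 41 or NRCWE-047 54 µg replicate 43.

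**Figure D3:**
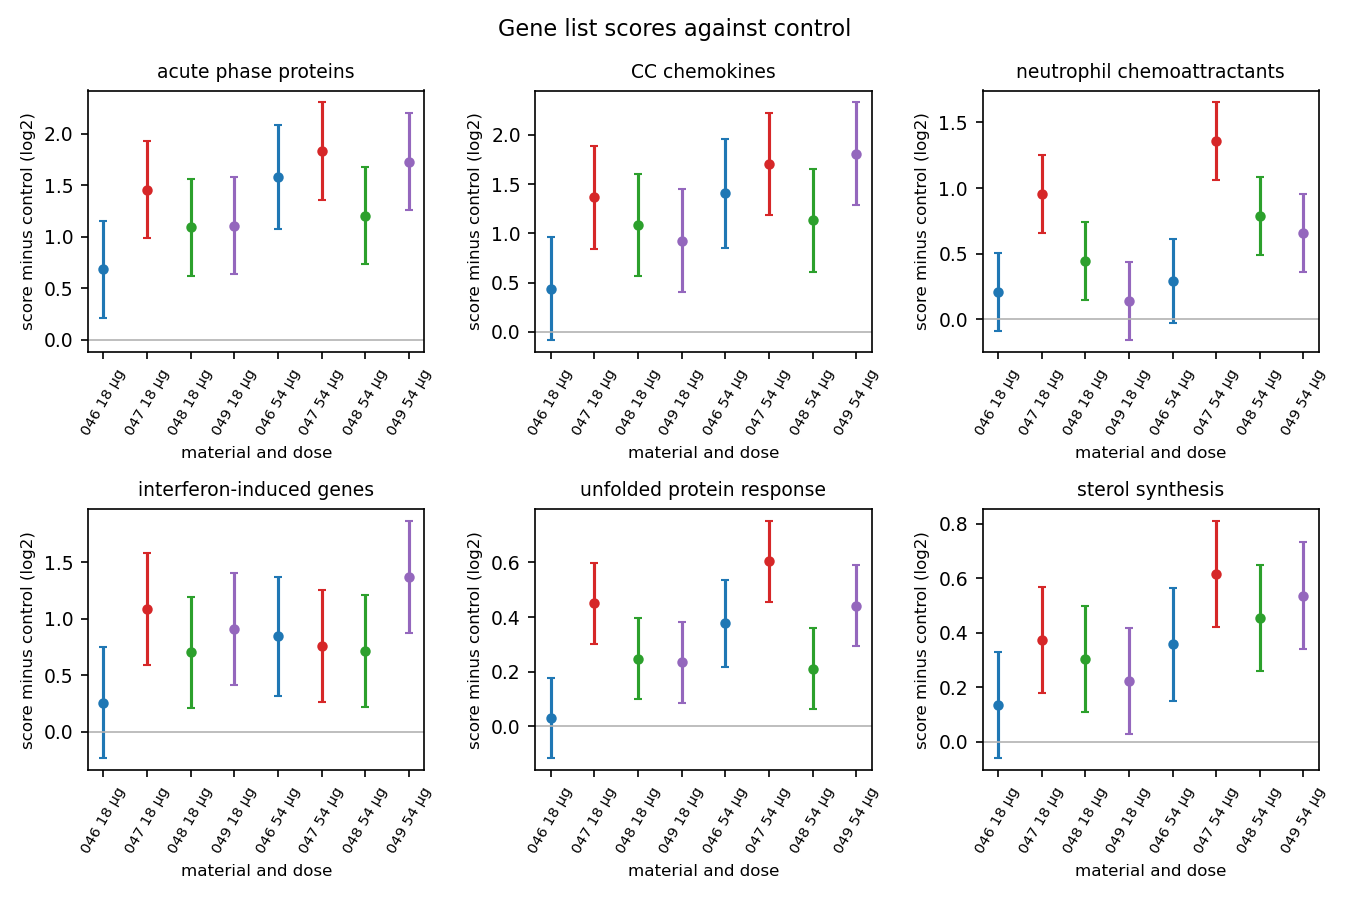
Score of 6 gene lists (mean log2 ratio of the list's genes, minus control) by material and dose, with 95% intervals from the model over all 45 arrays. At 54 µg neutrophil chemoattractants stand at 1.36 with NRCWE-047, and interferon-induced genes at 1.37 with NRCWE-049.

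Changes against control were shared between materials. At 54 µg NRCWE-047 and NRCWE-049 had 865 higher and 398 lower calls in common, with 1 opposite; independent lists of these sizes would share 57.2 and 15.7. NRCWE-046 shared 391 and 70 with NRCWE-047 (16.7 and 2.03 if independent) and 445 and 92 with NRCWE-049 (25.1 and 2.44). NRCWE-048 shared 57 and 10 with NRCWE-046 (1.16 and 0.0519), 73 and 17 with NRCWE-047 (2.65 and 0.335) and 77 and 15 with NRCWE-049 (3.99 and 0.402). At 18 µg NRCWE-047 shared 84 higher and 9 lower with NRCWE-048 (0.87 and 0.0175) and 81 and 8 with NRCWE-049 (1.47 and 0.0809; 1 opposite), and NRCWE-048 shared 87 and 11 with NRCWE-049 (0.859 and 0.0496). All 8 comparisons use the same controls. Simulated arrays with no effect and shared controls gave a median of 0 shared calls over 20 draws in every pair, with a highest value of 156 for NRCWE-046 and NRCWE-049 at 54 µg. These draws were fitted with only the pair and its controls, whereas the observed calls come from the fit of all groups. Real groups also gave fewer calls with only the groups of a contrast in the fit. The simulated and observed shared calls are therefore not on a like footing.

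Across genes, which are not independent replicates, the changes at 54 µg correlated with r = 0.82 for NRCWE-046 and NRCWE-049, 0.81 for NRCWE-047 and NRCWE-048, 0.78 for NRCWE-047 and NRCWE-049, 0.71 for NRCWE-048 and NRCWE-049, 0.67 for NRCWE-046 and NRCWE-047 and 0.63 for NRCWE-046 and NRCWE-048. Arrays simulated with no effect and shared controls gave median r values of 0.43, 0.51, 0.50, 0.43, 0.42 and 0.43 over 100 simulations. Their highest values were 0.81, 0.85, 0.87, 0.84, 0.88 and 0.86, so that all but the first observed correlation lie within the simulated range. The simulations drew on the deviations of all 45 arrays, slide 10 included, so this range holds more than the effect of shared controls. The covariances exceeded the simulated ones by 0.0403, 0.0287, 0.0415, 0.028, 0.0291 and 0.0165. With the controls split between the pair of materials the median r over 10 splits was 0.45, 0.40, 0.44, 0.33, 0.27 and 0.19, and the shared calls had medians of 116.5, 0, 144.5, 0, 45.5 and 0. Each of these fits held a single group with part of the controls, so it called fewer genes. NRCWE-048 itself had a median of 0 calls there, so its medians of 0 shared calls say nothing about sharing. At 18 µg NRCWE-047, NRCWE-048 and NRCWE-049 gave r between 0.69 and 0.79 (simulated medians 0.45 to 0.49, highest 0.81 to 0.88, covariance differences 0.0189 to 0.02, split medians 0.28 to 0.29), and with the controls split the shared calls had a median of 0 in every pair (highest 0, 2 and 2). The materials' own calls in these split fits had medians of only 11, 0 or 7.5, and 29, so few shared calls were possible. NRCWE-046 at 18 µg gave 0.37, 0.42 and 0.37 with NRCWE-047, NRCWE-048 and NRCWE-049, near the simulated 0.51, 0.39 and 0.48, with covariance differences of -5.94e-05, 0.00233 and 0.00122 and split medians of -0.12, -0.08 and -0.10.

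Between 18 and 54 µg, 8 genes changed with NRCWE-049 and 0 with each of the other materials. With NRCWE-049, Il6 rose by 1.78 (SE 0.34, adjusted p = 0.0303, higher in 5 of 5 animals), Il1b by 1.59 (SE 0.30) and Nos2, the inducible nitric oxide synthase, by 1.00 (SE 0.18), while Gabarapl1, a gene of autophagy, fell by 0.77 (SE 0.12) on the log2 scale. Of 17 cytokines 2 rose (6 adjusted over the list alone; list adjusted p = 3.36e-06), and the CC chemokine list rose with 0 of 13 members called (6 adjusted over the list alone; list adjusted p = 5.36e-09). The other 4 calls with NRCWE-049 were higher and are not named by the rule used here. Under a slide block 4 were called, 2 of them among the 8, and the adjusted p was 0.242 for Il6, 0.182 for Il1b and 0.196 for Nos2, against 0.0236 for Gabarapl1; without slide 10 there were 46 calls. Limma called 0 on the lung channel alone, and 1 each with the scanner log ratio and with groups by the treatment characteristic. It called 13 in the authors' value table and 43 with only the groups of the contrast in the fit. Within 2 slides all 8 kept their direction. The count was 4, 5, 1 and 2 without NRCWE-049 18 µg replicates 1, 17, 26 and 27, 15, 18 and 0 without NRCWE-049 54 µg replicates 3, 23 and 40, and 17 without control 33. It was 14 without NRCWE-047 18 µg replicate 5 or NRCWE-046 18 µg replicate 42, 17 without NRCWE-048 54 µg replicate 20 and 13 without NRCWE-047 54 µg replicate 43.

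For the other materials limma called 0 genes between doses at adjusted p under 0.05. Unadjusted p values under 0.05 numbered 2858 with NRCWE-046, 1569 with NRCWE-047 and 1454 with NRCWE-048, and the smallest adjusted p values were 0.103, 0.332 and 0.507. The acute phase list was higher at 54 µg than at 18 µg with NRCWE-046 (8 of 20 adjusted over the list alone; list adjusted p = 1.19e-07, adjusted p = 0.138 with an estimated correlation) and NRCWE-047 (1 of 20; list adjusted p = 0.000756, adjusted p = 0.372 with an estimated correlation). The NRCWE-046 count was 2 without NRCWE-048 54 µg replicate 14 or NRCWE-046 54 µg replicate 25, and the NRCWE-047 count was 1 without NRCWE-048 54 µg replicate 14. Dose effects were not shown to differ between materials: limma called 0 genes, with 1423 at an unadjusted p under 0.05, and 1 without NRCWE-049 54 µg replicate 3.

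At 54 µg, 32 genes differed between the 4 materials, led by clock genes, Cxcl5 and Tmem171. Cxcl5 was higher with NRCWE-047 than with NRCWE-046 by 3.80 (SE 0.54, adjusted p = 0.000254, 5 of 5 animals above the NRCWE-046 mean), and the matrix gene Spon2 by 2.24 (SE 0.43). Arntl, which encodes the clock activator BMAL1, was higher by 2.36 (SE 0.43), while Dbp at -3.93 (SE 0.68), Nr1d2 at -1.99 (SE 0.35) and Tef at -1.63 (SE 0.23), all clock-controlled, were lower. Of 16 clock genes 6 were lower and 1 higher with NRCWE-047 than with NRCWE-046 (10 and 4 adjusted over the list alone; list adjusted p = 3.97e-08), and 2 of 7 neutrophil chemoattractants were higher (3 adjusted over the list alone; list adjusted p = 6.57e-10). NRCWE-049 against NRCWE-047 showed the reverse: Dbp at 4.00 (SE 0.64), Nr1d1 at 2.41 (SE 0.46), Arntl at -2.21 (SE 0.40) and Cxcl5 at -2.72 (SE 0.51). With slide as a block these 4 had adjusted p values of 0.0518, 0.0928, 0.161 and 0.152, and Tmem171 at -1.53 (SE 0.21) kept its call (adjusted p = 0.00471). The interferon-induced list was higher with NRCWE-049 than with NRCWE-047 (3 of 21 adjusted over the list alone; list adjusted p = 1.84e-12, adjusted p = 0.242 with an estimated correlation).

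Against NRCWE-048 at 54 µg, NRCWE-049 had higher collagens, Col3a1 by 1.02 (SE 0.19) and Col1a1 by 0.77 (SE 0.15), and higher Nos2 at 0.91 (SE 0.18), with lower Gsta3 at -1.25 (SE 0.22). Of 21 matrix genes 2 were higher (7 adjusted over the list alone; list adjusted p = 2.66e-07, adjusted p = 0.164 with an estimated correlation). With slide as a block Nos2 and Col1a1 had adjusted p values of 0.0647 and 0.066. NRCWE-048 against NRCWE-047 gave 3 calls, all lower: Creld2 at -0.82 (SE 0.12), Manf at -0.78 (SE 0.14), both of the unfolded protein response, and Cxcl3 at -0.74 (SE 0.13). NRCWE-049 against NRCWE-046 gave 1 call, with 2 calls under a slide block and 2 without slide 10. NRCWE-048 against NRCWE-046 gave 0 in limma, with 1498 at an unadjusted p under 0.05 and 1 call without slide 10.

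The F test at 54 µg called 32 genes (49 with slide as a block, 74 without slide 10), and 48 genes differed in at least 1 pair (87 and 127). On the lung channel alone these counts fell to 10 and 15. The pairs gave 33 calls for NRCWE-047 against NRCWE-046 (57 with the block, 110 without slide 10), 14 for NRCWE-049 against NRCWE-047 (5 and 34), 10 for NRCWE-049 against NRCWE-048 (25 and 5) and 3 for NRCWE-048 against NRCWE-047 (8 and 6). Within slides that hold both materials the called genes kept their direction in 100% of cases, except 90 to 100% for NRCWE-049 against NRCWE-048. The F test count was 18, 14, 20 and 19 without NRCWE-047 54 µg replicates 4, 11, 18 and 28, 20 without NRCWE-048 54 µg replicate 14, 18 and 20 without NRCWE-046 54 µg replicates 19 and 38, and 21 without NRCWE-049 54 µg replicate 36. The count over pairs was 31 without NRCWE-047 54 µg replicate 4 or NRCWE-049 54 µg replicate 10, 28 without NRCWE-047 54 µg replicate 11, and 29 and 26 without NRCWE-046 54 µg replicates 19 and 38.

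At 18 µg, 29 genes differed between the materials, with Foxs1, Tmem171 and the clock genes Nr1d2, Tef and Dbp at the smallest p values. Against NRCWE-046, NRCWE-047 had higher Cxcl5 by 2.85 (SE 0.51, adjusted p = 0.00451, 5 of 5 animals above the NRCWE-046 mean), Saa2 by 2.29 (SE 0.51), Arntl by 2.00 (SE 0.40) and Hspa5 by 1.19 (SE 0.20), and lower Dbp at -3.59 (SE 0.64), Nr1d1 at -2.12 (SE 0.46) and Nr1d2 at -2.02 (SE 0.33). Of 16 unfolded protein response genes 4 were higher (8 adjusted over the list alone; list adjusted p = 3.27e-12). Of 16 clock genes 5 were lower and 4 higher (6 and 4 adjusted over the list alone; list adjusted p = 0.00195, adjusted p = 0.111 with an estimated correlation). NRCWE-049 against NRCWE-047 gave Dbp at 4.06 (SE 0.64), Nr1d2 at 2.43 (SE 0.33), Arntl at -2.56 (SE 0.40), Spon2 at -2.03 (SE 0.40) and Cxcl5 at -3.23 (SE 0.51). NRCWE-049 against NRCWE-046 gave 1 call, Vmn2r48 at 0.83 (SE 0.13), carried by 1 of 2 probes and with an adjusted p of 0.206 under a slide block. This pair had 0 calls in limma with the block and 11 without slide 10, and 4148 genes at an unadjusted p under 0.05 with all arrays. The smallest F test adjusted p values were 0.000123 for Foxs1 and Tmem171, whose means were 0.66 and 0.90 above control with NRCWE-047 and -0.44 and -0.81 with NRCWE-049.

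The F test at 18 µg called 29 genes (49 with slide as a block, 73 without slide 10), and 59 genes differed in at least 1 pair (127 and 159). NRCWE-047 against NRCWE-046 gave 46 calls (120 and 121) and NRCWE-049 against NRCWE-047 gave 28 (27 and 67). NRCWE-048 gave 0 calls in limma against NRCWE-046, NRCWE-047 and NRCWE-049, with 2152, 824 and 1333 genes at an unadjusted p under 0.05. There was 1 call against NRCWE-046 with the slide block and 1 against NRCWE-047 without slide 10. Within slides that hold both materials 100% of the called genes kept their direction. The F test count was 15, 16, 17 and 16 without NRCWE-047 18 µg replicates 5, 13, 22 and 32, and 18 without NRCWE-046 18 µg replicate 21, 30 or 34. The count over pairs was 36, 34, 37, 39 and 156 without NRCWE-047 18 µg replicates 5, 13, 22, 32 and 41.

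**Figure D4:**
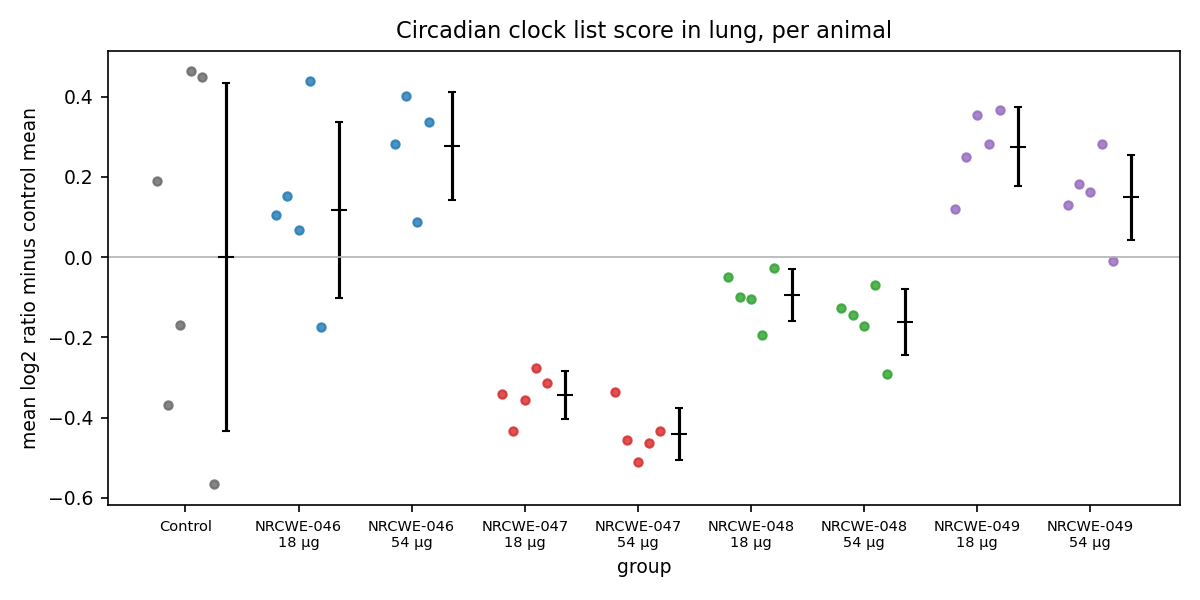
Circadian clock list score per animal by group (mean log2 ratio of 16 genes, minus the control mean); dots are animals, and the black mark with its bar is the group mean with its SD. All 10 NRCWE-047 animals lie below 0, as do 2 of the 19 NRCWE-046 and NRCWE-049 animals, and the controls run from -0.57 to 0.46.

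Over both doses the clock score was lower with NRCWE-047 than with NRCWE-046 and NRCWE-049 by -0.60 (95% interval -0.75 to -0.44). This grouping was chosen after the clock genes had been seen in the pairs of materials, so it is a description of them and no further test. The score was lower on 6 of 6 slides holding both kinds of array, by -0.26 to -0.73. Against control the NRCWE-047 difference was -0.39 (-0.59 to -0.19), and NRCWE-048 lay below NRCWE-046 and NRCWE-049 by -0.33 (-0.49 to -0.18).

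Cardiac muscle markers varied widely between animals. The score of 10 cardiac genes ran from -1.83 to 2.76 log2 units around the control mean. On this scale 11 arrays in 7 groups stood above 1 and 22 arrays in 9 groups below -1. The lowest correlation between any pair of these genes over the 45 arrays was 0.60. With NRCWE-046 at 18 µg all 5 arrays lay below the control mean (score -1.45, SD 0.44, against an SD of 1.89 in the controls), and the list was lower with 0 of 10 members called (0 adjusted over the list alone; list adjusted p = 2.67e-05, adjusted p = 0.476 with an estimated correlation). The list also passed as higher at 54 than at 18 µg with NRCWE-046 (list adjusted p = 0.0468, adjusted p = 0.757 with an estimated correlation) and NRCWE-047 (list adjusted p = 0.00481, adjusted p = 0.579 with an estimated correlation), and as lower with NRCWE-048 than with NRCWE-047 at 54 µg (list adjusted p = 0.0162, adjusted p = 0.565 with an estimated correlation). With slide as a block the dose comparison of NRCWE-046 had an adjusted p of 0.129 in camera.

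On slide 10, which holds 4 arrays of 4 groups, the median lung signal was 609 to 1210 against 110 to 198.5 on the other slides, and the reference signal 441 to 808 against 67.5 to 139.

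**Figure D5:**
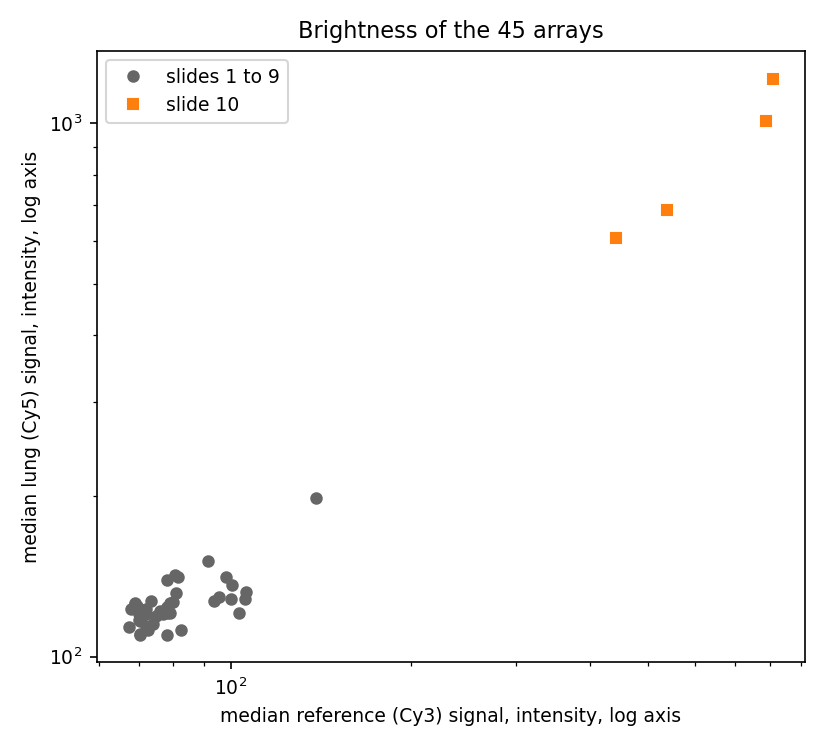
Median lung (Cy5) against reference (Cy3) signal of each array, in intensity units on log axes; points are arrays, with the 4 arrays of slide 10 as orange squares. Slide 10 lies at 609 to 1210 in the lung channel and 441 to 808 in the reference channel, the other arrays at 110 to 198.5 and 67.5 to 139.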

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

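For slide 10 the brightness ratio was chosen after the pattern was seen and the correlation test by title before; the correlation test by the treatment characteristic was also chosen after. The tests on replicate 14 were chosen before its result was seen. For the clock, the tests on the hour and on inflammation were chosen after the result was seen and the slide test before.

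The 4 arrays of slide 10 (replicates 42, 43, 44 and 45, of 4 different groups by their titles) stand apart on the first principal component, which holds 29% of the variance. Their lowest reference signal was 3.17 times the highest elsewhere, and 77.8 to 87.1% of their spots were well above background against 46.7 to 77.5%. Brighter labelling, hybridisation or scanning of the whole slide is consistent with that, since the reference RNA is the same on all arrays. The animals' groups by title do not account for it: the deviations from each array's own group correlated at 0.72 or more across genes in all 6 pairs, up to 0.88, against a 95th percentile of 0.32 for pairs on different slides and a median of 0.17 over 88 pairs within other slides. By the treatment characteristic, which differs from the title on 3 of these arrays, all 4 carry NRCWE-047; the animals' groups by that label do not account for it either, as deviations from the NRCWE-047 arrays of the same dose on other slides still correlated at 0.79 and 0.82 in the 2 pairs of treated arrays of different doses.

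Replicate 14 of NRCWE-048 at 54 µg lies at the level of the controls on a score over many genes. Over 379 genes higher with the other 3 materials at 54 µg its score was 0.08, where the controls ran from -0.17 to 0.30 with a second highest of 0.06, and the other 4 animals of its group from 0.30 to 0.87. Single genes differed: Cxcl5 at 1.89 and Il1b at 0.99 lay above the highest control (1.37 and 0.93). Its Saa3 at 0.89, Lcn2 at 0.26 and Timp1 at -0.25 lay within the control range. Little or none of the dose in this animal, or a wrong label, would be consistent with 0.08. An exchange with a control cannot be told from this, as control 33 at 0.30 reaches the lowest other animal of the group, and 5 of 38 other treated arrays lie below it (lowest 0.10). A dim array is not the cause: 56.9% of its spots were well above background, against 46.7 to 58.9% on the rest of slide 3.

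Clock gene scores were lower with NRCWE-047 than with NRCWE-046 and NRCWE-049. Lungs taken at another hour of the day would be consistent with the opposite shifts of 1.1 (0.87 to 1.33) in Arntl, Npas2, Clock and Nfil3 and of -1.73 (-2.10 to -1.35) in the 7 genes that peak with Dbp. The strength of the inflammatory response cannot be told apart from this: NRCWE-047 and NRCWE-049 at 54 µg differed by -0.59 (-0.84 to -0.34) in the clock score with acute phase scores 0.10 apart (-0.39 to 0.60), but neutrophil chemoattractant scores were 0.70 (0.39 to 1.01) and NF-kB feedback scores 0.20 (0.04 to 0.37) higher with NRCWE-047. The slide does not account for it, with lower NRCWE-047 scores on 6 of 6 slides. Whether the exposure itself shifts the clock was not tested and stays open.

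Arrays were also regrouped at random, in 100 splits with the real one included, and the genes called were counted. Splits as large as the real one numbered 1 for NRCWE-049 at 18 µg (309 genes, highest other 103) and 1 at 54 µg (2500, highest other 785), which makes chance unlikely at this number of splits but does not exclude it. They numbered 2 for NRCWE-047 at 18 µg (255, highest other 426), where the other split exchanges replicate 41 and control 45. They numbered 2 for NRCWE-048 at 18 µg (150, highest other 157), whose other split sets 4 treated animals with controls 33 and 37 against replicate 16 and the remaining controls, close to the real one. They numbered 2 for NRCWE-046 at 54 µg (600, highest other 632), whose other split keeps all 4 treated animals together with controls 33 and 37.

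Splits that follow slide 10 called more. For NRCWE-047 at 54 µg 2 splits were as large (1797, highest other 1802); the other brings replicate 43 and control 45 of slide 10 together, and the slide block gives 3720 for the real groups. For NRCWE-048 at 54 µg 2 were as large (96, highest other 2032); the other brings replicate 44 and control 45 together and puts replicate 14 with the controls, so this size points to sample structure, with 559 under the slide block. For NRCWE-046 at 18 µg 6 were as large (4, highest other 2983); the highest puts replicate 42 and control 45 together with controls 9, 12 and 29, so it too points to sample structure, with 3 under the slide block, and chance cannot be excluded for its 4 genes.

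For dose effects 1 split was as large with NRCWE-049 (8 genes, highest other 4), and all 100 with NRCWE-046, NRCWE-047 and NRCWE-048 (0 genes in limma, highest others 1, 2 and 3, with 2858, 1569 and 1454 at an unadjusted p under 0.05). Differences between materials gave 2 splits as large at 18 µg in the F test (29, highest other 85) and 6 over pairs (59, highest other 529), so chance cannot be excluded for the pairs at 18 µg. At 54 µg they gave 2 in the F test (32, highest other 40) and 2 over pairs (48, highest other 440). For the dose effect between materials all 100 were as large (0 in limma, highest other 24, 1423 at an unadjusted p under 0.05). For lists 1 split was as large against control (163, highest other 144), 1 between doses (76, highest other 64) and 1 between materials (182, highest other 154). The other splits had medians of 71, 37 and 104. Many lists thus pass in camera under random groups too. The arrays kept their real exposures and slide effects in these splits, so random groups can differ in them. The medians are therefore no rate of false calls. A list's adjusted p at the preset correlation should still not stand alone, as far fewer lists passed with an estimated correlation.

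Single animals stood outside their group in 29 of 279 tests (18 genes and 13 lists in 9 groups), where 13.9 would arise by chance. Values are log2 units from the control mean, with the range of the rest of the group. Control 33 had Saa3 at 3.75 (rest -1.41 to -0.44), Timp1 at 2.03 (-1.05 to -0.10) and NF-kB feedback genes at 0.26 (-0.09 to -0.02). Its Saa3 and its Saa1 of 1.86 lay within the range of NRCWE-046 at 18 µg (3.69 to 4.46 and 1.15 to 2.30). Its Lcn2 of 1.07 and Cxcl5 of 0.22 lay below that group (1.24 to 1.58 and 0.71 to 1.19). This array is part of every comparison with control, and whether the animal was exposed was not tested. Control 45 had Cxcl2 at 0.46 (-0.18 to -0.01), Spp1 at 0.99 (-0.34 to 0.09) and alveolar macrophage markers at -1.35 (-0.03 to 0.61). Control 37 had Hmox1 at 1.32 (-0.41 to -0.07), and control 9 sterol synthesis at -0.09 (0 to 0.05).

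At 18 µg, NRCWE-046 replicate 42 had Cxcl1 at 2.86 (-0.18 to 0.41), xenobiotic metabolism at -0.88 (-0.07 to 0.08), monocyte markers at -0.58 (0.06 to 0.31), alveolar macrophage markers at -1.89 (0.14 to 0.56) and cardiac muscle markers at -0.67 (-1.75 to -1.55). NRCWE-047 replicate 41 had Saa3 at 4.64 (6.76 to 7.50), Timp1 at 1.5 (3.27 to 3.82) and NF-kB feedback genes at 0.20 (0.43 to 0.52). NRCWE-048 replicate 16 had Il1b at 0.29 (0.80 to 0.96). NRCWE-049 replicate 39 had alveolar macrophage markers at 0.20 (-0.25 to -0.19), and replicate 1 cardiac muscle markers at 2.57 (-1.78 to -0.77).

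At 54 µg, NRCWE-046 replicate 15 had Saa1 at 5.03 (4.29 to 4.36), Ccl2 at 2.63 (1.64 to 1.76) and Ccl7 at 3.18 (2.05 to 2.16). NRCWE-047 replicate 18 had Cxcl5 at 5.73 (4.51 to 4.76) and Lcn2 at 2.58 (1.83 to 2.05), and replicate 43 CC chemokines at 1.26 (1.77 to 1.90) and monocyte markers at -0.01 (0.49 to 0.65). NRCWE-048 replicate 14 had Lcn2 at 0.26 (1.73 to 2.17), and replicate 31 cardiac muscle markers at 2.76 (-1.77 to -0.70). NRCWE-049 replicate 40 had Cxcl1 at 2.46 (0.92 to 1.29).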

How the results depend on the processing

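Counts below are genes called, given where an alternative moved a count by more than 1.5 times. Of the values for called lists, named genes and counts, 23766, 28819 and 1054 stayed the same, 1483 lists and 2285 named genes became weaker, 58 named genes became stronger, and 222 counts moved. Most that stayed the same, 18406, 21504 and 843, come from leaving out 1 array, often one outside the comparison. A further 421, 511 and 21 come from Aquantile normalization, which leaves the ratios unchanged. These totals are therefore no measure of stability. One list reversed: endothelial cell markers for NRCWE-047 against NRCWE-046 at 18 µg stood at -0.338 with groups by the treatment characteristic.

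With no background correction NRCWE-046 at 18 µg against control gave 1. The scanner log ratio gave 0 for NRCWE-046, 98 for NRCWE-048 and 201 for NRCWE-049 at 18 µg against control, and 1 and 1 between doses for NRCWE-048 and NRCWE-049. The lung channel alone gave 126, 85 and 64 for NRCWE-047, NRCWE-048 and NRCWE-049 at 18 µg, 281, 1108, 60 and 1517 for NRCWE-046 to NRCWE-049 at 54 µg, 0 between doses of NRCWE-049, 9 and 10 in the F tests at 18 and 54 µg and 28 and 15 over pairs. The authors' value table gave 1 for NRCWE-046 at 18 µg and 13 between doses of NRCWE-049. The filter on 23 arrays gave 535 for NRCWE-049 at 18 µg and 16 between its doses, and the mean of a gene's probes 13 between doses of NRCWE-049. No filter on dim probes moved no count.

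With slide as a fixed block the counts were 700 and 602 for NRCWE-047 and NRCWE-048 at 18 µg, 1298, 3720, 559 and 4679 for NRCWE-046 to NRCWE-049 at 54 µg, 4 between doses of NRCWE-049, 49 and 49 in the F tests at 18 and 54 µg, 127 and 87 over pairs, and 151 for the list score per array. With slide as a random block they were 7, 737, 504 and 737 at 18 µg, 1267, 3404, 582 and 4035 at 54 µg, 7 and 24 between doses of NRCWE-046 and NRCWE-049, 91 and 69 in the F tests and 203 and 113 over pairs. With scan date as a block they were 677 and 656 for NRCWE-047 and NRCWE-048 at 18 µg, 1160, 3802, 599 and 4874 at 54 µg, 78 and 51 in the F tests, 173 and 84 over pairs and 135 for the list score.

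Array weights gave 11, 1451, 804 and 1319 at 18 µg, 2041, 4237, 1044 and 4270 at 54 µg, 415, 3 and 53 between doses of NRCWE-046, NRCWE-047 and NRCWE-049, 752 and 153 in the F tests, 1 for the dose effect between materials, and 1869 and 250 over pairs. With only the groups of the contrast in the fit the counts were 0, 6, 0 and 54 at 18 µg, 317, 987, 1 and 1560 at 54 µg, 6 and 43 between doses of NRCWE-046 and NRCWE-049, 45 in the F test at 18 µg and 184 over pairs at 18 µg.

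Without the 4 arrays with conflicting labels the counts were 0 and 198 for NRCWE-046 and NRCWE-049 at 18 µg, 4272 and 282 for NRCWE-047 and NRCWE-048 at 54 µg, 60 and 65 in the F tests and 119 and 144 over pairs. With groups by the treatment characteristic they were 0, 80 and 65 for NRCWE-046, NRCWE-048 and NRCWE-049 at 18 µg, 3791 and 46 for NRCWE-047 and NRCWE-048 at 54 µg, 1 between doses of NRCWE-049, 9 in the F test at 18 µg and 33 over pairs at 18 µg. Without slide 10 they were 0, 493, 280 and 590 at 18 µg, 1102, 3343, 452 and 4172 at 54 µg, 46 between doses of NRCWE-049, 73 and 74 in the F tests and 159 and 127 over pairs.

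Camera with an estimated correlation called 48 lists against control, 8 between doses and 18 between materials. Of 421 called lists 74 stayed with it. Of the same lists 82 became weaker with the slide block, 64 with scan date, 61 with the scanner log ratio, 56 with the lung channel alone, 97 with groups by the treatment characteristic, 59 without the conflicting arrays and 48 without slide 10.

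With each array left out in turn the counts ran from 0 to 7, 67 to 609, 14 to 248 and 37 to 589 for NRCWE-046 to NRCWE-049 at 18 µg, and from 214 to 799, 1240 to 2634, 13 to 508 and 1733 to 3073 at 54 µg. Between doses they ran from 0 to 2, 0 to 1, 0 to 0 and 0 to 18. The F tests ran from 15 to 38 at 18 µg, 14 to 38 at 54 µg and 0 to 1 for the dose effect between materials, and pairs from 34 to 156 and 26 to 68. Lists called ran from 158 to 181 against control, 69 to 78 between doses and 172 to 193 between materials, and the list score per array from 27 to 93. The list score count was 27, 28, 35 and 36 without controls 9, 12, 29 and 37, against 69 with all arrays. In this round 102 counts moved, and 539 lists and 1474 named genes became weaker.

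Aquantile normalization leaves each array's ratios unchanged and so tests nothing. Camera was not run with the random block or with array weights. No paired analysis was possible because no label pairs animals across groups, and replicate numbers are not shared. Slides hold at most 1 array of a group, and slide enters as a block above.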

Other observations

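Complement and inflammasome lists passed with all 4 materials at 54 µg. Of 14 measured genes 4 rose with NRCWE-046 (4 adjusted over the list alone; list adjusted p = 2.54e-08, adjusted p = 0.0915 with an estimated correlation), 4 with NRCWE-047 (4 adjusted over the list alone; list adjusted p = 5.02e-06, adjusted p = 0.154 with an estimated correlation) and 4 with NRCWE-049 (4 adjusted over the list alone; list adjusted p = 2.89e-05, adjusted p = 0.182 with an estimated correlation). C3, the central complement component, stood at 1.57 (SE 0.24), 1.58 (SE 0.23) and 1.43 (SE 0.23), and factor B (Cfb) at 1.63 (SE 0.30), 1.70 (SE 0.28) and 1.63 (SE 0.28). Of 9 inflammasome genes 3 rose with each of these materials (3 adjusted over the list alone in each; list adjusted p = 0.000586, 0.00279 and 0.000248), with Mefv, which encodes pyrin, at 1.55 (SE 0.35), 1.76 (SE 0.33) and 2.42 (SE 0.33). With NRCWE-048, 0 of 14 complement genes (4 adjusted over the list alone; list adjusted p = 0.00227, adjusted p = 0.451 with an estimated correlation) and 1 of 9 inflammasome genes were called (3 adjusted over the list alone; list adjusted p = 0.000891). With NRCWE-046, NRCWE-047 and NRCWE-049 the alarmin Il33 stood at 1.47 (SE 0.28), 1.43 (SE 0.26) and 1.92 (SE 0.26).

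Matrix proteases passed as a list with all 4 materials at 54 µg, with members called with NRCWE-047 and NRCWE-049. Of 14 genes 6 rose with NRCWE-047 (6 and 1 lower adjusted over the list alone; list adjusted p = 1.05e-05), among them Adamts4 at 1.46 (SE 0.25), Mmp3 at 1.33 (SE 0.24) and Mmp9 at 0.92 (SE 0.18). With NRCWE-049 4 rose and 1 fell (7 and 1 adjusted over the list alone; list adjusted p = 0.000217), with Mmp3 at 1.44 (SE 0.24), Adamts1 at 1.05 (SE 0.26) and the gelatinase Mmp2 at -0.85 (SE 0.16). With NRCWE-046 and NRCWE-048 0 members were called (4 and 1 higher, 1 and 1 lower adjusted over the list alone; list adjusted p = 0.00138 and 0.0471, adjusted p = 0.0862 and 0.31 with an estimated correlation). With slide as a block the NRCWE-048 list had an adjusted p of 0.154 in camera. Heat shock genes were lower with NRCWE-048 than with NRCWE-047 at 54 µg as a list, with 0 of 9 members called (7 adjusted over the list alone; list adjusted p = 3.4e-12).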
